A study of Mus musculus with 3 samples.

How the data were processed

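RNA was extracted with the RNeasy micro kit from LKS cells sorted from bone marrow, and libraries were made with NEB kits, per the labels' protocols. Groups were taken from the sample titles and the series design text: 2 WT libraries and 1 CD73 KO library. Nothing in the labels says whether the WT libraries came from separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The labels also describe the samples as LLP cells, a term not explained in the sources used here, and do not state whether the sorted cells were of donor or recipient origin.

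The deposited counts are whole numbers per RefSeq transcript, and the deposited FPKM values are given per transcript beside them. The submitters' processing notes name STAR and the mm10 genome build without versions or roles. The counting tool, the tool that estimated FPKM and the use of strand are not given in the sources used here. Each file held 42574 transcript rows for 24982 gene symbols, of which 8313 had more than 1 row, and 0 rows named no gene. Transcripts of a gene repeat their shared reads, so the gene count was taken as the highest count over a gene's rows. As a check of the units, the total reads implied by FPKM and count in single-transcript genes with at least 30 counts had medians of 358613, 321421 and 260231, against gene-level totals of 361638, 324954 and 264704. The FPKM values were otherwise used only as an alternative.

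Depth was low, with 1911, 1752 and 1317 genes reaching 50 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The floor for a gene at 0 was 3 counts over the group. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the groups, TMM scaling, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05). The WT pair leaves 1 residual degree of freedom, so the spread was in effect pooled across genes, and the KO library was assumed to vary like the WT pair. The common biological coefficient of variation was 0.81. The spread used in the tests varied with abundance and was far smaller for abundant genes. SE was thus 0.08 for Rn45s, the most abundant gene, and 1.37 for Sv2a. SE was the absolute log2 fold change divided by the square root of F, and was not given where a group was at 0. CPM values are scaled with TMM factors. The median log2 fold change over all tested genes was -0.31, and -0.11 over the 6296 genes with a count in every library.

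The 34 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most alternative settings. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01). Lists with under 3 tested members were left out, which left 30. Where gene p-values were adjusted over a list alone, no correction was made over the lists. Beside camera stand camera with an estimated correlation, fry, and the percentile of the median among 10000 random lists matched in 20 expression bins, which cannot give a p under 0.0002. The p-values of camera at the preset correlation and of the matched lists rest on the spread among genes, not between libraries. They come out too small where the genes of a list vary together more than assumed. A size rule without a test counted genes with at least 50 counts in some library that differed in KO from each WT library by at least 2-fold in the same direction, on TMM-scaled CPM plus 1.

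Named genes were Nt5e; per direction up to 12 genes past the threshold with at least 50 counts in some library and KO outside both WT values, ranked by fold and filled from the size rule, leaving out predicted genes, pseudogenes and mitochondrial genes; and from each list its members past the threshold and up to 4 of its most abundant members. Some abundant members are not named for length, and 1 is not reported here. Genes outside the rule were chosen after their values were seen: Irf8, Nt5c2, H2-T23, Car1, Epor, Ermap, Clec9a, Plbd1, Clec10a, Cst3, Ifi30, Naaa, Itgax, Siglech, Batf3, Cd209a, Zbtb46, Cd79a, Xist, and those named in the closing section.

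The gene and list tests were tested on simulated data, 5 simulations of the KO against WT comparison on 6967 to 7012 genes, each with 200 changed genes. They recovered 12% of genes raised 4-fold, 87.6% of genes raised 16-fold, 0.8% of genes lowered 4-fold and 19.2% of genes lowered 16-fold. There were 6 false calls in total and 0 lists called. Power for lower genes was thus small, and the count of 0 lower genes stands beside it. The changed genes were drawn from the more abundant tested genes only, so recovery over all tested genes was not measured. Genes were simulated independently, and the KO library was given the spread of the WT pair. The 0 lists called therefore cannot show how the list test behaves with correlated genes or a more variable KO library.

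Alternatives were DESeq2 1.42.0 size factors, upper-quartile and total-count scaling, looser and stricter filters, DESeq2, limma voom, the edgeR likelihood ratio test and other size thresholds; the mean over transcripts, FPKM with limma and genes with a count in every library were added after seeing the data. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names, which held 98.0% of the symbols. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.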

Results

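Gene expression was measured by RNA sequencing in LKS cells, the Lin-negative, Kit-positive, Sca1-positive fraction of mouse bone marrow that holds haematopoietic stem and early progenitor cells. The cells were sorted from wild-type (WT) recipient mice, with 2 libraries, and from recipients lacking CD73, with 1 library (the KO library). CD73, encoded by Nt5e, is the cell-surface enzyme that turns extracellular AMP into adenosine. The labels speak of recipients without saying whether the sorted cells came from donor or recipient. The libraries held 361638 gene-level counts in WT replicate 1, 324954 in WT replicate 2 and 264704 in the KO library, in which 9501, 9519 and 8474 genes had at least 1 count. The WT libraries differed from each other by more than the counting error of independent reads, with a chi-square of 13.8 per gene, against 14.3 and 15.8 for the KO library and each WT library. A total of 3 counts, the upper limit that a count of 0 allows, corresponds to 8.30, 9.23 and 11.3 CPM (counts scaled to library size), here on library totals without the TMM factors used for all other CPM values, in the 3 libraries in that order.

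The targeted gene could not check the label. Nt5e (chromosome 9, 88327197 to 88372092, mm10) had 0 counts in all 3 libraries, so its expression was below detection at this depth in WT and KO cells alike.

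The comparison of the KO library with the WT pair addressed which genes LKS cells express differently in a CD73-deficient recipient. MHC class II genes, whose products present peptides to CD4 T cells, were higher in the KO library. H2-Ab1, the class II beta chain, rose from 49.8 ± 22.9 CPM (SD, n = 2) in WT to 770 CPM in KO (24, 11 and 201 counts in WT replicate 1, WT replicate 2 and KO). H2-Aa, the class II alpha chain, had 0, 9 and 106 counts in the same order, and H2-DMb2, part of the complex that loads peptide onto class II molecules, had 3, 2 and 102. Both passed the test. Outside this group, Rpl38, a protein of the large ribosomal subunit, rose from 218 ± 131 CPM (SD, n = 2) to 1318 CPM.

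In all, 8 of 7984 tested genes were higher and 0 were lower at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 282 higher and 520 lower genes. The log2 fold change was 3.94 (SE 0.81, adjusted p 0.0044) for H2-Ab1, 4.89 (SE 1.16, adjusted p 0.031) for H2-Aa and 5.69 (SE 1.24, adjusted p 0.0087) for H2-DMb2. It was 2.60 (SE 0.55, adjusted p 0.0072) for Rpl38 (113, 41 and 344 counts). Rn45s, the precursor of ribosomal RNA, was the most abundant gene of each library and rose by 0.61 (SE 0.08, adjusted p 6.7e-10), from 4795 and 4731 counts in WT to 5481 in the smaller KO library. Its SE and p rest on the spread that the fit gave to the most abundant genes. Sv2a, a synaptic vesicle glycoprotein, had 0, 4 and 80 counts (log2 fold change 5.61, SE 1.37, adjusted p 0.043). Prdm9, a histone methyltransferase of meiosis, and Oplah, the 5-oxoprolinase, had 0 counts in both WT libraries and 57 and 52 in KO. Against a floor of 3 counts over the WT pair these were at least 50.3-fold and 45.9-fold higher, with adjusted p 0.021 and 0.035. The log2 fold change of Rpl38 was 2.08 against WT replicate 1 alone and 3.41 against WT replicate 2 alone. That of H2-Aa was 3.88 and that of Sv2a 4.62 against WT replicate 2 alone, and both had 0 counts in WT replicate 1. The calls rest on a single KO library, which is assumed to vary like the WT pair, and none of the 8 was called by DESeq2, which called 0 genes (621 at an unadjusted p under 0.05). With at least 10 counts required in every library or 50 in any, the edgeR test also called 0 genes (340 at an unadjusted p under 0.05), and with the mean count over transcripts in place of the highest it called Rn45s alone.

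The MHC class II genes lie on chromosome 17 of mm10: H2-DMb2 at 34143307 to 34151555, H2-Ab1 at 34257689 to 34269419, H2-Aa at 34282744 to 34287823 and H2-Eb1 at 34305867 to 34316674. Cd74, the invariant chain that escorts class II molecules, lies apart from them on chromosome 18 at 60803848 to 60812652. Rpl38 is on chromosome 11 at 114668524 to 114672331, Sv2a on chromosome 3 at 96181151 to 96195521, Prdm9 on chromosome 17 at 15543079 to 15564354 and Oplah on chromosome 15 at 76296601 to 76328015. All 9 genes are annotated as protein-coding, and the counts cover their annotated RefSeq transcripts. H2-DMb2 has a near-identical neighbour, H2-DMb1, and Rn45s is a multi-copy gene, so their counts are uncertain. Oplah is overlapped on the opposite strand by Exosc4 (2, 10 and 22 counts), and reads of such pairs cannot be told apart where strand use is not stated.

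The antigen presentation list was higher as a group, with a positive log2 fold change in all 18 tested members and a median log2 fold change of 1.003. Adjusted over all genes tested, H2-Aa and H2-Ab1 rose; adjusted over the list alone, 7 members rose and 0 fell. These also included H2-Eb1 (19, 21 and 156 counts), Cd74 (7, 150 and 252), and the class I genes H2-K1 (1219, 890 and 1211), H2-Q4 (337, 351 and 520) and H2-T23 (81, 83 and 187, named after its values were seen). Their counts are from libraries of unequal depth, and the CPM of H2-K1 was 3034 ± 448 (SD, n = 2) in WT and 4639 in KO. H2-D1 (227, 149 and 267 counts) and B2m (451, 355 and 397), the shared light chain of class I, did not pass. The reads of class I genes are partly shared between paralogs, so the split between H2-K1, H2-D1, H2-Q4 and H2-T23 is uncertain. The list passed with camera at its preset correlation (adjusted p 0.00039). It did not pass with an estimated correlation (adjusted p = 0.95) or with fry (adjusted p = 0.31). These are also the smallest adjusted p values that the 2 tests gave any of the 30 lists. With 1 residual degree of freedom they had little power, so they cannot decide for or against the call. The list's median lay at percentile 100 of 10000 random lists matched on expression (adjusted p 0.0030). This p and that of camera at the preset correlation take genes as the units, so neither measures the spread between libraries. Without the class II genes, Cd74 and Ciita, a subset chosen after the values were seen, 12 of 12 tested members were positive, with a median of 0.88 (camera p 0.0061, unadjusted). Against WT replicate 1 alone the median of the whole list was 1.15, with 17 of 18 members positive, and against WT replicate 2 alone it was 1.11, with 18 of 18.

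**Figure D1:**
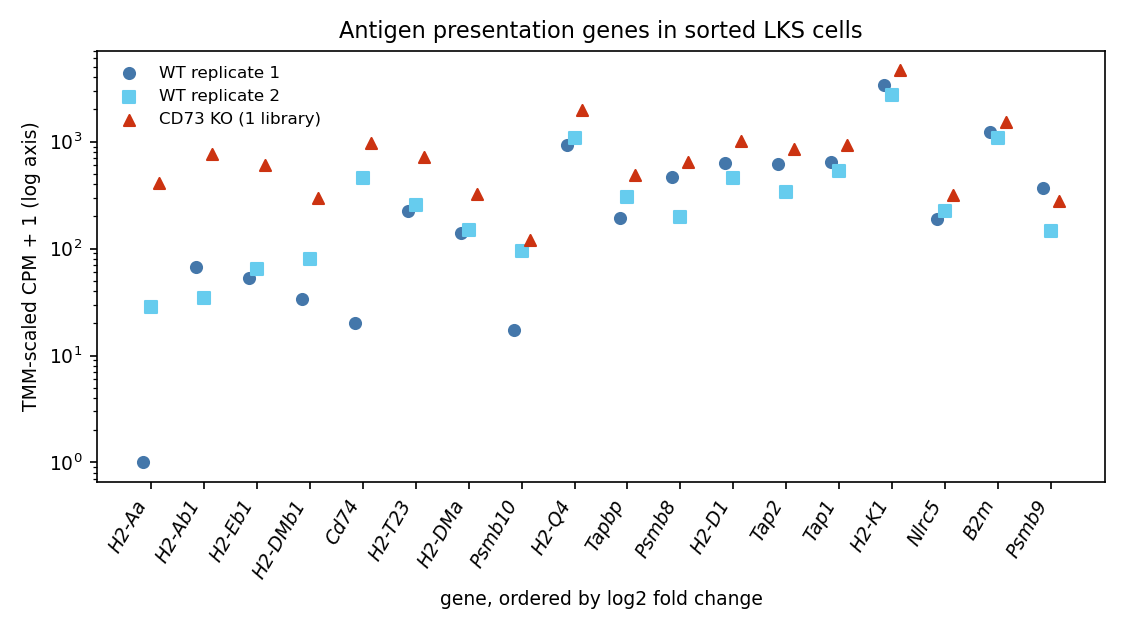
Expression of the 18 tested antigen presentation genes in each library, as TMM-scaled CPM plus 1 on a log axis, with 1 point per library and no error bars because the KO group has 1 library. H2-Ab1 sits at 770 CPM in KO against 49.8 ± 22.9 (SD, n = 2) in WT, and Cd74 at 19.2 and 458 CPM in the WT libraries and 965 in KO.

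The dendritic cell list was also higher, with 7 of 8 tested members positive and a median log2 fold change of 2.98 (camera, preset correlation, adjusted p 0.0031; adjusted p = 0.95 with an estimated correlation). It shares 4 tested genes with the antigen presentation list, the class II genes H2-Aa, H2-Ab1 and H2-Eb1 and Cd74, so it is not independent of that list. Without these genes, a subset chosen after the values were seen, 3 of the 4 tested members left were positive, with a median of 2.16, and the list no longer passed camera (p 0.077, unadjusted), while its median lay at percentile 99.93 of matched random lists (p 0.0016, unadjusted). Over all genes 2 members rose, H2-Aa and H2-Ab1, and adjusted over the list alone 5 did. The fifth was Irf8, a transcription factor of dendritic cell and monocyte development, with 1, 37 and 126 counts (named after its values were seen; log2 fold change 2.11 against WT replicate 2 alone). The receptor Flt3 had 104, 151 and 56 counts, and Siglech, Batf3, Cd209a and Zbtb46, used as markers of mature dendritic cells, had 0 counts in every library. Of dendritic cell markers outside the list, Clec9a had 0, 0 and 27 counts and Plbd1 1, 2 and 9, while Cst3 had 91, 86 and 85, Ifi30 5, 28 and 16, Naaa 0, 17 and 14, and Clec10a 32, 17 and 0. Itgax, a member of the list, had 4, 0 and 0.

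Genes of myeloid priming gave mixed values. Mpo, the myeloperoxidase of neutrophil granules, had 692, 667 and 992 counts (log2 fold change 0.96, SE 0.25, adjusted p 0.067), and Calr, an endoplasmic reticulum chaperone, had 366, 311 and 634 (1.32, SE 0.34, adjusted p 0.066). Elane had 74, 212 and 273 counts, and Prtn3 220, 216 and 164. Prtn3 is overlapped on the opposite strand by Plppr3 (320, 178 and 344 counts), so its counts are uncertain. Over all genes 0 of 18 tested members passed, and adjusted over the list alone Mpo, Calr and Irf8 rose. The list median was 0.20 (camera adjusted p 0.18), 0.93 against WT replicate 1 alone, with 15 of 18 members positive, and 0.41 against WT replicate 2 alone, with 10 of 18. In the lymphoid priming list 10 of 13 tested members had a negative log2 fold change, with a median of -0.67, and the list did not pass (camera adjusted p 0.78). Dntt, the terminal transferase of early lymphoid progenitors, had 39, 87 and 0 counts, at least 16.2-fold lower against a floor of 3 KO counts, and passed over the list alone (adjusted p 0.0030) but not over all genes (0.077). Flt3, Ikzf1 (54, 172 and 43), Cd27 (114, 69 and 44) and Cd34 (230, 194 and 110) did not pass. In the stem cell signature 0 of 23 tested members passed and the median was -0.22 (camera adjusted p 0.83). Kit, part of the sorting gate, had 573 ± 83.4 CPM (SD, n = 2) in WT and 563 in KO, while Meis1 had 279 ± 84.1 and 119, and Gata2 284 ± 73.1 and 107.

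Interferon response genes had a median log2 fold change of 0.93 over 24 tested members, 16 of them positive, with 0 past the test and a camera adjusted p of 0.054. Igtp had 29, 19 and 59 counts, whereas Oas2 had 83, 54 and 8. The median was 1.45 against WT replicate 1 alone and 0.50 against WT replicate 2 alone. Over the 9 interferon members with at least 50 counts in some library the camera adjusted p was 0.89. It was 0.23 over the 20 members with a count in every library. Erythroid genes had a median of 1.76 over 7 tested members, none past the test (camera adjusted p 0.14), with 0.79 against WT replicate 1 alone. Against WT replicate 2 alone it was 6.52, a fitted value and no bound, since Car1, Epor, Ermap and Aqp1 had 0 counts there. Over the 3 members with a count in every library camera's direction was down (adjusted p 0.96). Hbb-bt, a beta globin, had 151, 42 and 114 counts. Among ribosomal proteins 31 of 40 had a positive fold change, Rpl38 alone passed, and the median was 0.29 (camera adjusted p 0.18). Proliferation genes did not pass: the medians were -0.21 for G1/S genes (25 tested, adjusted p 0.89) and 0.27 for G2/M genes (28 tested, adjusted p 0.81), and Mki67 had 1405 ± 225 CPM (SD, n = 2) in WT and 1559 in KO. In the adenosine pathway 0 of 13 tested members passed over all genes (median 0.16, or 0.56 and 0.03 against WT replicates 1 and 2 alone; adjusted p 0.79). Adjusted over the list alone, Nt5c2, a cytosolic nucleotidase named after its values were seen, rose, with 2, 16 and 113 counts. The 4 most abundant members, Ampd2, Slc29a1, Pnp and Slc28a2, did not pass.

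Among the remaining lists, camera gave adjusted p values of 0.38 for mature neutrophil genes (median -1.77, or -1.26 with genes at 0 set to their bound, and -0.84 against WT replicate 1 alone), 0.83 for monocyte and macrophage genes (median -1.34, or -1.29 at the bound) and 0.54 for apoptosis regulators (median 0.57). It gave 0.62 for the TNF and NF-kB response (median -0.69), 0.78 for immediate early and heat shock genes (median -0.66) and 0.81 for the unfolded protein and integrated stress response (median -0.46), cAMP-responsive genes (median -0.60), p53 targets (median -0.04), replication-dependent histones (median 0.25), nuclear-encoded oxidative phosphorylation (median -0.05) and nuclear-retained and ribosomal RNA (median 0.20). It gave 0.85 for Myc and ribosome biogenesis (median -0.24) and 0.89 for megakaryocyte genes (median -0.31), mast cell, basophil and eosinophil genes (median -0.21, or -0.42 and -1.02 against WT replicates 1 and 2 alone), cell cycle inhibition and quiescence (median 0.05), the antioxidant response (median -0.28), homing and niche adhesion (median -0.22) and sex-linked genes (median -0.09). Glycolysis and hypoxia genes had a median of -0.25 (adjusted p 0.94). Against a single WT library the median changed sign for G1/S, cell cycle inhibition, histone, p53, oxidative phosphorylation, glycolysis, Myc, homing, megakaryocyte and sex-linked genes, none of which passed. Camera compares the mean test statistic of a list, and not its median, with that of the other genes. Its direction was down for cell cycle inhibition and quiescence, with a median of 0.05 and a mean log2 CPM difference of -0.45. It was up despite a negative median for G1/S genes, p53 targets, oxidative phosphorylation, the antioxidant response, glycolysis and hypoxia, and Myc and ribosome biogenesis.

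**Figure D2:**
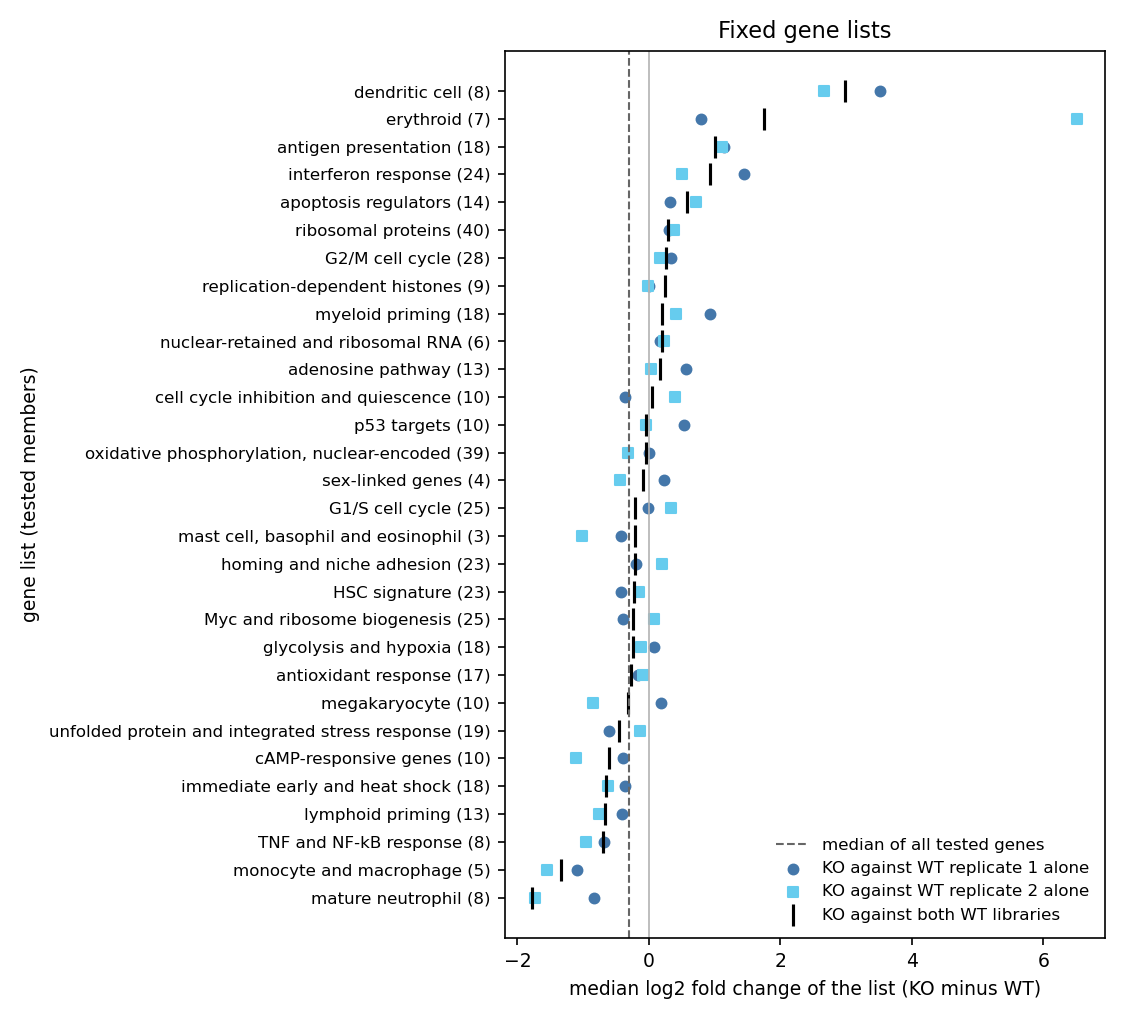
Median log2 fold change (KO minus WT) of each of the 30 tested gene lists, from both WT libraries (black bars) and from each WT library alone (points), with the number of tested members in brackets; the dashed line is the median of all tested genes, -0.31. The antigen presentation and dendritic cell medians, 1.003 and 2.98, lie above that line against each WT library.

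Apart from the test, 769 of the 2831 genes with at least 50 counts in some library differed from each WT library by at least 2-fold in the same direction in KO, 270 higher and 499 lower. The same count with WT replicate 1 set against the other libraries was 529 (296 higher, 233 lower), and with WT replicate 2 it was 688 (360 higher, 328 lower). Among the 271 genes with at least 200 counts in some library this excess was not seen: 15 genes stood apart in KO (6 higher, 9 lower), 15 in WT replicate 1 (10 higher, 5 lower) and 14 in WT replicate 2 (4 higher, 10 lower). Of the 499 lower genes 92 had 0 KO counts, against 16 for each WT library. Genes that stood out by size on the higher side without passing the test were Prss57 (0, 1 and 60 counts), Ccdc14 (0, 2 and 61), Pole2 (0, 4 and 60) and Rsu1 (3, 4 and 59). On the lower side, Scap (63, 69 and 0 counts), an escort protein of sterol-regulated transcription factors, and Crtc2 (62, 55 and 0), a coactivator of CREB, were at least 16.7-fold and 14.7-fold lower. Samm50, Osbpl7, Fance, Nup153, Nelfcd, Nt5dc2, Pglyrp2, Atp6v0e and Gmppa also had 0 KO counts and were at least 12.1-fold to 16.6-fold lower. None of these passed the test, for which the adjusted p of the lower genes ranged from 0.068 to 0.15. Nelfcd is overlapped on the opposite strand by Ctsz (38, 48 and 18 counts).

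**Figure D3:**
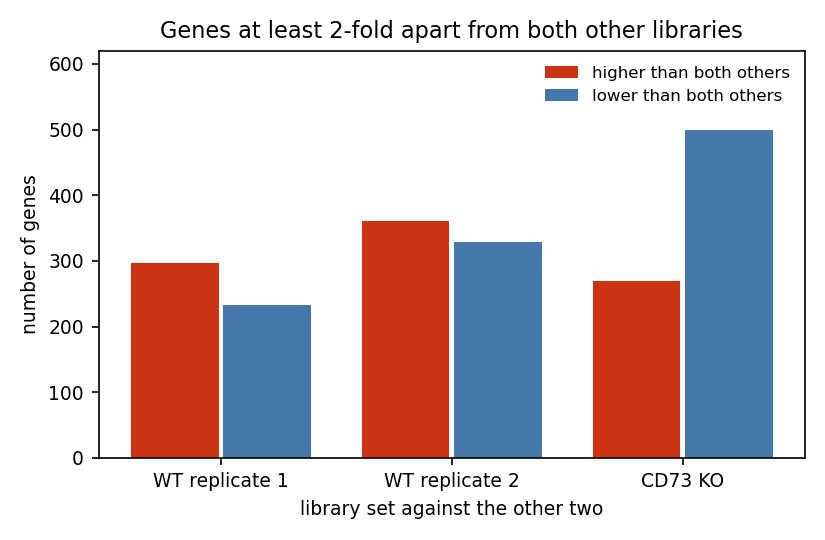
Number of genes, among 2831 with at least 50 counts in some library, that were at least 2-fold higher or lower than both other libraries, for each library in turn. The KO library has 270 higher and 499 lower genes, WT replicate 1 has 296 and 233, and WT replicate 2 has 360 and 328.

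Markers of mature cells outside the gate were present at differing levels. The summed CPM of the mature neutrophil list was 855, 1261 and 441 in WT replicate 1, WT replicate 2 and KO, and that of the erythroid list 910, 666 and 1130. The summed CPM of the B lineage list was 16.5, 73.3 and 53.6, that of the T and NK lineage list 179, 6.11 and 0, and that of the stroma and endothelium list 113, 101 and 38.3. The B lineage, T and NK lineage and stroma lists had under 3 tested members and were not tested, and no gene of the mitochondrial genome was analysed here. The B cell gene Cd79a had 0 counts in every library, and the macrophage gene Lyz2 had 32, 112 and 20. Of the sex-linked genes, Xist had 0, 3 and 9 counts, Eif2s3y 28, 19 and 18, Kdm5d 18, 17 and 0, Uty 1, 17 and 6, and Ddx3y 10, 1 and 11.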

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

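The settings with mean counts over transcripts, with FPKM and with genes counted in every library, and the size rule without each WT library, were chosen after seeing the data. The 8 genes called by edgeR became 3 with upper-quartile scaling, 4 without a filter, 4 over genes with a count in every library, 4 with voom and 1 with mean counts over transcripts. They became 0 with the stricter filter, 0 with DESeq2 (621 at an unadjusted p under 0.05) and 0 with FPKM and limma at a pseudocount of 1, of 0.1, or without a filter (1094, 1537 and 1112). The likelihood ratio test called 12 (11 higher and 1 lower), of which 6 were among the 8. Voom called Cd74 (adjusted p 0.0067, range over the alternatives up to 0.98). The cause of these losses was not tested. Voom and FPKM at a pseudocount of 1 moved the median of all genes by 0.18 and 0.16. The 769 genes set apart by size became 490 at 3-fold, 2220 at 20 counts and 15 at 200 counts. They ranged from 1034 to 1119 without a WT library, where a gene had to differ from the other WT library only. That rule is easier to meet, so the rise says nothing of stability. The 2 lists became 0 with an estimated correlation and 0 with fry, tests with little power at 1 residual degree of freedom. They became 4 with matched lists (the erythroid and interferon lists added) and 3 with mean counts over transcripts (the interferon list added, camera adjusted p 0.044). The antigen presentation and dendritic cell lists kept their call with total-count scaling, with abundant members, over genes counted in every library and with mean counts. The interferon list did not pass with abundant members (camera adjusted p 0.89) or over genes counted in every library (0.23).

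Of 80 named genes, the log2 fold change reversed under another scaling or tool only for Irf9 with total-count scaling (-0.0071) and for Prtn3 with upper-quartile (-0.057) and total-count scaling (-0.046). No paired analysis was possible because the KO group has 1 library with no replicate number. Leaving out a WT library leaves 1 against 1 with no residual degree of freedom, so genes and camera had no test. Without WT replicate 1 the fold changed sign for 3 of the 80 genes (Irf9, Prtn3 and Slc28a2) and without WT replicate 2 for 5 (Ikzf1, Kit, Mki67, Mcm6 and Mcm3), 0 of them called. Depth limits what can be said of genes with few counts, Nt5e among them.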

Other observations

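The tests of a chance split, of B cells, of macrophages, of single-gene noise and of depth were chosen only after the result was seen, and so was the reading of markers at 0 counts against their 3-count limit.

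In the glycolysis and hypoxia list 9 of 18 tested members had a positive and 9 a negative log2 fold change, and none passed the test. Of its 4 most abundant members, Ldha, lactate dehydrogenase A, had 699 ± 56.6 CPM (SD, n = 2) in WT and 215 in KO (log2 fold change -1.69, SE 0.66, edgeR adjusted p 0.27), Pkm 888 ± 120 and 387, and Gpi1 860 ± 18.8 and 464. Aldoa had 407 ± 113 and 536. Among other single genes, the nuclear RNA Malat1 had 555, 421 and 776 counts in WT replicate 1, WT replicate 2 and KO (log2 fold change 1.09, SE 0.30, adjusted p 0.079), and Neat1 had 307, 237 and 133. The integrin Itgb3 had 50, 35 and 1 counts, the retinoblastoma family gene Rbl2 98, 34 and 1, and Cd47 101, 107 and 5. Adjusted over their lists alone, Rbl2 (0.017) and Cd47 (0.031) passed, as did Malat1 (0.00074). In the homing list that holds Cd47, the integrin Itgb7 passed in the other direction (37, 0 and 102 counts, 0.046). None of these genes passed over all genes, where the edgeR adjusted p of Rbl2 was 0.16. Ciita, the master regulator of class II transcription, had 0, 0 and 12 counts, too few to be tested.

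With each library in turn set against the other pair, the edgeR test called 8 genes for KO and at most 3 for a WT library, and camera at its preset correlation called 2 lists for KO and 0 for either WT library, although antigen presentation had an adjusted p of 0.065 with WT replicate 1 alone in that place. The 2 calls are lost with an estimated correlation (adjusted p = 0.95), where 1 residual degree of freedom left little power to call any list. In each case 1 of the 3 splits, the real one, reached the KO value, and 3 splits cannot give a share under 0.05.

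The higher class II genes could come from another cell type in the KO sort, although the gate removes lineage-positive cells. The summed CPM of 7 class II genes was 319 and 818 in WT and 3747 in KO. B cells, macrophages and plasmacytoid dendritic cells as the whole cause are argued against: the B cell markers summed to 276 CPM in KO and 220 and 348 in WT, mostly Cd37, and the macrophage markers to 80.4 in KO and 107 and 430 in WT, mostly Lyz2. The 7 plasmacytoid markers, Siglech among them, summed to 0 in every library, and the 3-count limit of 11.3 CPM in KO is far below the rise of 3178 CPM in class II genes. Mature conventional dendritic cells stay open: their 11 markers summed to 578 CPM in KO and 366 and 458 in WT. A sum above both WT libraries had been predicted for these cells before the values were seen, and was met. The prediction covered the sum only, and the single markers were picked for naming after their values were seen. Over the WT mean the sum rose by 167 CPM (1.40-fold), against 3178 CPM (6.59-fold) for class II genes. The met prediction therefore cannot show that these cells account for the class II rise. In WT replicate 1, WT replicate 2 and KO, Clec9a was at 0, 0 and 103 CPM and Plbd1 at 2.75, 6.11 and 34.5. Cst3, the most abundant, was at 250, 263 and 326, Naaa at 0, 51.9 and 53.6, and Ifi30 at 13.7, 85.5 and 61.3. Itgax was at 11, 0 and 0 and Clec10a at 88.0, 51.9 and 0, while Cd209a, Zbtb46, Ccr7 and Fscn1 had 0 counts. Noise in single genes stays open too, since the matched random lists (adjusted p 0.0030) restate the list's own result, and an effect of the CD73-deficient recipient is untested with 1 KO library.

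More genes were lower than higher in the KO library by size, 499 against 270, and 9 against 6 among genes with at least 200 counts, where WT replicate 2 had 10 against 4. For the number of genes detected, smaller depth as the whole cause is argued against. Thinned to 260000 counts, the KO library detected 8454 genes and the WT libraries 9329 and 9358. The size rule admits genes by raw counts and was not repeated on thinned counts, so depth stays open for the split by size. A few genes taking more of the counts is argued against for detection too. Without the 142 genes among the top 100 of any library, thinned to 206000 counts, the KO library detected 8331 genes and the WT libraries 9144 and 9192. The size rule was not repeated there either, so this cannot decide the split by size. Fewer RNA molecules captured could give the same picture and cannot be told apart from a difference in the cells: the scatter of KO counts against each WT library was 1.13 and 1.30 times that within the WT pair, between the bounds set for either reading. Cell numbers and RNA input are not analysed here.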
